A study of Mus musculus with 48 samples.

How the data were processed

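EU-labelled nascent RNA was measured in mouse embryonic stem cells, growing asynchronously or released from nocodazole. Per the labels' protocols, cells grew in Knockout DMEM with 15% FBS and LIF, were held in 100 ng/ml nocodazole for 6 h, collected by mitotic shake-off and washed 3 times, and labelled RNA was captured with a Click-iT kit and made into libraries with a KAPA Hyper Prep kit. Whether the 2 libraries of a clone came from separate cultures was not given in the sources used here. Trim Galore 0.60, STAR 2.7.1a, RSEM 1.3.0 and the mm10 build are listed in the submitters' processing notes, with no role or order.

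The values used were whole-number counts per gene symbol, as deposited by the authors in 1 table per library, not normalized. Each table held 55291 gene symbols and 5 counter entries (reads in no feature, ambiguous reads and the like), which were left out of library totals and tests. Reads in no feature made up 90.2 to 94.0% of a table's total (median 91.4%), and ambiguous reads 0.129 to 0.262%. The design, fixed before the data were examined, allowed for estimated counts, but none were rounded. Whether the counting used strand was not given in the sources used here. Of the symbols, 53292 matched GENCODE M21 names and took their mm10 coordinates from it.

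Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The 2 libraries of each clone and condition were summed, giving 24 sums, since the clone was the replicate. Features with enough counts (filterByExpr, minimum count 10 and total 15) numbered 23874, scaling was by TMM, and edgeR's quasi-likelihood test (robust) was used with Benjamini-Hochberg adjustment at 0.05. MD and R42A were compared in a fit of 12 group means. Times were compared within each genotype, and the interaction with asynchronous cells was tested, in a fit with a term per clone. The common biological coefficient of variation was 0.127 and 0.112 in these fits. Replicate libraries of a clone differed by more than counting noise (chi-square per degree of freedom 1.09 to 26.8), so no library was counted as a duplicate.

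Before the data were examined the design, the alternatives, the gene lists and the rule for named features were written down. Named features passed the adjusted threshold, averaged at least 2 CPM, had both clones on the same side and bore no provisional name, and the 6 with the largest fold in each direction were taken (8 for R42A at 45 min). Smarce1 and up to 4 members of a described list with the smallest adjusted p could be added. Only part of these are given for some comparisons. Some features that met the rule are not reported here. The 25 lists were SWI/SNF subunits, pluripotency, formative and primed pluripotency, two-cell-like, immediate early and serum response, FGF-ERK feedback, Wnt and Nodal targets, G2/M, G1/S, replication-dependent histones, ribosomal proteins, ribosome biogenesis, p53 targets, heat shock, unfolded protein and amino acid response, interferon response, mitochondrially encoded, Hox clusters, imprinted genes, actin cytoskeleton and adhesion, and markers of mesoderm, endoderm, neural cells, trophoblast and fibroblasts. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison.

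The alternatives were each clone, each library and each replicate number left out, no clone term, the 48 libraries fitted singly, limma-voom with a correlation within clones, no filter, the replicate number as a block, DESeq2's size factors in edgeR, the sums of 1 condition alone, DESeq2 1.42.0, and features activated at 90 min. After the data were seen, fits without the 90 min libraries, without MD 90 min replicate 1, without CT010467.2 and the mitochondrially encoded features, and with features nested in a gene on the other strand credited to that gene were added.

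On simulated counts for the 23874 features, with 100 features changed by each fold, the MD against R42A test at 45 min recovered 56% of 2-fold and 92% of 4-fold changes, with 2.63% of 152 calls false. The R42A test of 45 against 0 min recovered 52% and 96%, with 10.8% of 166 calls false, and the interaction test at 45 min 17% and 79%, with 9.43% of 106 calls false. The false share of the last pair exceeded the nominal 5%.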

Results

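Newly made RNA was sequenced from mouse embryonic stem cells (strain 129S5/SvEvBrd) labelled briefly with 5-ethynyluridine (EU). Cells build this uridine analogue into nascent RNA, which can be captured. The cells carried SMARCE1, a subunit of the SWI/SNF (BAF) chromatin remodelling complex, in a form set up for degradation during mitosis (Smarce1-MD, here MD; clones MD09 and MD30) or in the R42A form of that construct, taken here as the control (clones A04 and A10). Each clone was sampled while growing asynchronously and on release (0 min) from nocodazole, a microtubule inhibitor that arrests cells in mitosis, and 45, 90, 180 and 240 min later. There were 2 libraries per clone and condition, 12 groups of 4 and 48 in all. Counts assigned to genes ranged from 630119 to 3885219 per library. The lowest totals were in MD cells at 90 min (630119 to 1518400) and in both genotypes at 0 min (762327 to 1022255).

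The clone was the replicate (n = 2 clones per genotype and condition), and the p-values measure only the spread between these clones. Fold changes are log2 values from edgeR's quasi-likelihood test ± standard error, with Benjamini-Hochberg adjusted p, and levels are CPM, counts scaled to a common library total, ± SD over 2 clones. Where a group held 0 counts, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its 95% interval, and both cover counting error only. Many reads were credited to features inside a gene on the other strand, and the strand setting was not given in the sources used here. Every value below is a count credited to a feature, which need not measure transcription of the gene of that name. Coordinates are mm10, GENCODE M21.

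**Figure D1:**
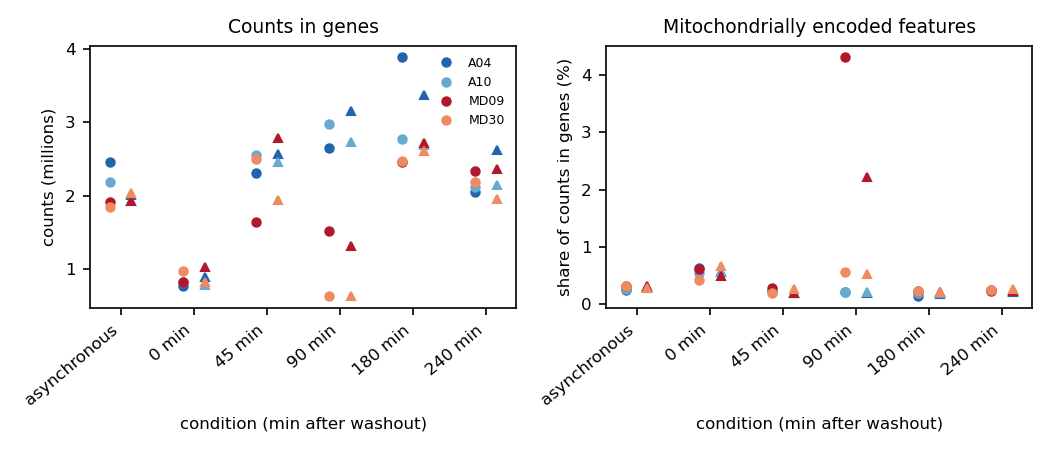
Counts in genes per library (left) and the share of those counts in mitochondrially encoded features (right, percent) by condition, with circles for replicate 1, triangles for replicate 2 and a colour for each clone. MD libraries at 90 min held 0.529 to 4.31% of their counts in mitochondrially encoded features, the 0 min libraries 0.427 to 0.657%, and all other libraries 0.138 to 0.31%.

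The first comparison asked how nascent transcription differed between MD and R42A cells in asynchronous culture. Smarce1 itself stood at 26.9 ± 1.91 CPM in MD and 39.3 ± 4.08 CPM in R42A cells (log2 fold change -0.55 ± 0.19, adjusted p = 0.0509), from 42 to 95 counts per library. This value missed the threshold, passed it in 5 alternatives (adjusted p from 0.0223 to 0.0498) and missed it in all others run, with log2 -0.30, adjusted p = 0.618 without replicate 1, -0.38, adjusted p = 0.258 without A04 replicate 1 and -0.40, adjusted p = 0.383 without clone A04. Ccl17, a chemokine gene (chromosome 8, 94810453 to 94812036), was lower in MD (4.65 ± 2.14 against 34.3 ± 8.88 CPM; -2.88 ± 0.29, adjusted p = 1.36e-08). In the HoxC cluster, Hoxc13 (chromosome 15, 102921103 to 102928814; 2.74 ± 0.967 against 20.7 ± 6.22 CPM; -2.89 ± 0.33, adjusted p = 1.42e-07) and the long noncoding RNA Hotair (1.3 ± 0.231 against 12.7 ± 0.304 CPM; -3.26 ± 0.43, adjusted p = 1.83e-06) were both lower. Grb10, an imprinted adaptor gene of growth factor receptors, was higher (2.57 ± 0.20, adjusted p = 3.36e-11).

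Across all 23874 features tested, 3135 differed, 1237 higher and 1898 lower in MD, 720 and 743 of them by over 1 log2 unit. Large increases were found for Ugt2b1, a glucuronosyltransferase gene (41.9-fold, interval 7.11 to 1694), its neighbour Ugt2b34 (3.74 ± 0.47) and the microRNA feature Mir6381, which lies inside Gbp2 on the other strand (21.4-fold, interval 5.58 to 183). The protease gene Tmprss13 (3.99 ± 0.53), the calicin gene Ccin (3.91 ± 0.52) and the interleukin gene Il5 (13.3-fold, interval 3.32 to 115) were others, all with adjusted p from 9.91e-07 to 0.00262. Besides Hotair, Hoxc13 and Ccl17, the largest decreases were those of Spata31d1a (-3.80 ± 0.53, adjusted p = 4.15e-06), the defensin gene Defb36 (10.4-fold, interval 3.27 to 53.3, lower, adjusted p = 0.0068) and Ccdc201 (-2.97 ± 0.54, adjusted p = 0.000204).

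Of 17 imprinted genes 5 were higher and none lower (7 higher adjusted over the list alone; camera adjusted p = 0.000468, adjusted p = 0.216 with an estimated correlation). Grb10 and H19 (2.55 ± 0.57, adjusted p = 0.00213) were among them. Of 13 genes of formative and primed pluripotency, 4 were higher and none lower (5 adjusted over the list alone; camera adjusted p = 0.00167, adjusted p = 0.359 with an estimated correlation). Grhl2, a transcription factor of epithelial genes, stood at 0.97 ± 0.18, adjusted p = 0.000316. Actin and adhesion genes held 4 higher of 18 (4 adjusted over the list alone). Zyx (1.01 ± 0.23, adjusted p = 0.00207) and Tpm1 (0.88 ± 0.21, adjusted p = 0.00366) were among them. Among the 27 SWI/SNF subunits, Bcl7c was higher (0.74 ± 0.23, adjusted p = 0.0292), 3 were lower (1 and 4 adjusted over the list alone), Brd7 (-0.83 ± 0.21, adjusted p = 0.00575) and Smarcd3 (-0.75 ± 0.21, adjusted p = 0.0142) with the smallest p. Pluripotency genes held 1 higher, Dnmt3l (0.94 ± 0.19, adjusted p = 0.000499), and 2 lower of 29, with Tbx3 at -1.06 ± 0.23, adjusted p = 0.00137 (the same numbers adjusted over the list alone). Immediate early genes, the first to respond to growth factors, split into 2 higher, Ccn1 (2.29 ± 0.39, adjusted p = 9.49e-05) and Egr1 (1.12 ± 0.28, adjusted p = 0.00564), and 2 lower of 25, 2 and 2 adjusted over the list alone. Trophoblast markers held Tfap2c (1.34 ± 0.24, adjusted p = 0.000118) and Gata3 (1.92 ± 0.49, adjusted p = 0.0066) higher and 1 lower of 7 (2 and 2 adjusted over the list alone). Without MD09 replicate 2 the formative list held 1 higher and the imprinted list 3 (2 with DESeq2, 8 with no filter), and the lower counts of pluripotency, immediate early and trophoblast genes each lost 1 without A04 replicate 1, among other libraries. No set test in any comparison below held with an estimated correlation, and the lowest such adjusted p was 0.0613. With 1 clone left out, between 1315 and 2864 features differed.

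In cells held in mitosis (0 min), the comparison asked what differed before release. Smarce1 stood at 25.5 ± 1.54 CPM in MD and 35.4 ± 2.79 CPM in R42A cells (log2 -0.48 ± 0.22, adjusted p = 0.22). The pluripotency list held 7 of 29 genes lower in MD and none higher (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 2.22e-05, adjusted p = 0.475 with an estimated correlation). They included the transcription factor genes Tbx3 (-1.87 ± 0.29, adjusted p = 5.29e-05), Zfp42 (-0.91 ± 0.17, adjusted p = 0.000552), Klf4 (-1.06 ± 0.23, adjusted p = 0.00349) and Klf5 (-1.40 ± 0.32, adjusted p = 0.00467). Ank1, which encodes an ankyrin of the membrane skeleton (chromosome 8, 22974844 to 23150497), was the best measured of the large decreases (25.8 ± 6.36 against 182 ± 44.2 CPM; -2.82 ± 0.29, adjusted p = 1.72e-06). Its neighbour Nkx6-3, a homeobox gene (chromosome 8, 23153269 to 23158948), was lower as well (5.54 ± 2.22 against 53.6 ± 13.2 CPM; -3.26 ± 0.64, adjusted p = 0.00785).

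In total 1590 features differed, 886 higher and 704 lower. The olfactory receptor gene Olfr978 (at least 17.5-fold lower, from 12.8 ± 4.4 CPM in R42A; adjusted p = 3.84e-06), the transcription factor gene Pou4f2 (16.3-fold, interval 2.49 to 691, lower; adjusted p = 0.0141), the tubulin gene Tubb4a (-2.89 ± 0.79, adjusted p = 0.0236) and Zbed3 (-2.72 ± 0.49, adjusted p = 0.000394) completed the named decreases. The named increases were Fosl2, an AP-1 subunit gene (at least 5.71-fold), Mir6381 (at least 5.14-fold) and the myosin gene Myh7 (25.7-fold, interval 4.27 to 1048). The sterol transporter gene Npc1l1 (19.7-fold, interval 3.2 to 811), Treml2 (15.4-fold, interval 2.43 to 642) and Ugt2b34 (14.6-fold, interval 2.28 to 608) followed, all with adjusted p from 0.000394 to 0.038. Single libraries decided some of these calls: Pou4f2 was lost without A10 replicate 1 or MD09 replicate 2 (adjusted p from 0.0525 to 0.061), Ugt2b34 without MD30 replicate 1 (adjusted p = 0.0879), Tubb4a without A10 replicate 1 or 2, MD09 replicate 2, or MD30 replicate 2 (adjusted p from 0.0511 to 0.0859) and Treml2 without A04 replicate 1 or 2, A10 replicate 2, or MD09 replicate 1 or 2 (adjusted p from 0.0549 to 0.0915).

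Ribosomal protein genes held 5 lower and none higher of 77 (6 lower adjusted over the list alone), with a median of -0.35 (camera adjusted p = 3.25e-08, adjusted p = 0.475 with an estimated correlation). Heat shock genes held 2 lower of 11 (2 adjusted over the list alone; camera adjusted p = 0.0449, adjusted p = 0.475 with an estimated correlation). Of 28 G2/M genes, Mki67 (-0.84 ± 0.18, adjusted p = 0.0025) and Cdc20 (-0.82 ± 0.21, adjusted p = 0.0151) were lower and none higher, also when adjusted over the list alone. The G1/S list of 25 likewise held Mcm5 (-0.93 ± 0.21, adjusted p = 0.00386) and Gins2 (-0.62 ± 0.17, adjusted p = 0.0195) lower, the same number as adjusted over the list alone. The interferon list held Oasl2 higher (1.01 ± 0.26, adjusted p = 0.0153) of 10, and the p53 list held Ccng1 higher (1.14 ± 0.30, adjusted p = 0.0152) of 20, each the only member adjusted over its list alone too. Without A04 replicate 2 or A10 replicate 1 the pluripotency list held 4 lower, the heat shock list 1 and the ribosomal list 0 (0 also without MD30 replicate 2, and 2 without MD09 replicate 1 or with DESeq2). Ccng1 lost its call without MD09 replicate 1 (adjusted p = 0.0534), Gins2 without A10 replicate 1 (adjusted p = 0.0862) and Oasl2 without A04 replicate 2 (adjusted p = 0.0627). Leaving out 1 clone gave between 582 and 1007 features.

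At 45 min after release the comparison asked how the first transcription after mitosis differed. Smarce1 stood at 27.2 ± 5.49 CPM in MD and 50.3 ± 2.79 CPM in R42A cells, and was lower (log2 -0.88 ± 0.18, adjusted p = 0.000533). Lgi1, which encodes a secreted neuronal protein (chromosome 19, 38264536 to 38312214), was higher in MD (93.9 ± 4.48 against 7.14 ± 0.796 CPM; 3.71 ± 0.25, adjusted p = 1.26e-11), as was the galanin-like peptide gene Galp (37.4 ± 9.74 against 2.86 ± 1.8 CPM; 3.68 ± 0.28, adjusted p = 6.6e-11). The RAS-family gene Mras (chromosome 9, 99385420 to 99437381) was lower (13.6 ± 6.85 against 106 ± 45.2 CPM; -2.97 ± 0.31, adjusted p = 1.95e-06). Pluripotency genes held 8 lower and 2 higher of 29 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00393, adjusted p = 0.446 with an estimated correlation). Tbx3 (-1.66 ± 0.21, adjusted p = 8.88e-07), Klf5 (-1.04 ± 0.24, adjusted p = 0.00196) and Klf4 (-0.78 ± 0.19, adjusted p = 0.00344) were among them. Of 25 immediate early genes 6 were lower and none higher (8 lower adjusted over the list alone; camera adjusted p = 0.00393, adjusted p = 0.407 with an estimated correlation). Junb (-0.71 ± 0.17, adjusted p = 0.00287) and Maff (-0.61 ± 0.15, adjusted p = 0.00475) were among them.

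The total was 4201 features, 2451 higher and 1750 lower. DESeq2 with its own scaling gave 1512 higher and 1658 lower, and the fit without the 90 min libraries, chosen after the data were seen, gave 2138 higher and 2508 lower. Besides Lgi1 and Galp, the named increases were those of the receptor gene Mrgprd (8.22 ± 2.1 against 0.476 ± 0.391 CPM), Fam180a (3.27 ± 0.59), Prr33 (3.04 ± 0.60) and Mir142b (2.97 ± 0.63), which overlaps Mir142hg on the other strand (adjusted p from 3.21e-06 to 0.00365). Decreases beside Mras included those of Pou4f2 (-2.52 ± 0.51), Herpud1, a gene of endoplasmic reticulum protein quality control (-2.47 ± 0.52) and Vax2os (-2.33 ± 0.64), with adjusted p from 0.000667 to 0.0243. The Vax2os call was lost without MD09 replicate 2 or MD30 replicate 2 (adjusted p from 0.0529 to 0.0633).

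Feedback genes of FGF-ERK signalling held 3 lower of 11 (4 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.411 with an estimated correlation), or 5 with no filter. Spry4 (-0.79 ± 0.21, adjusted p = 0.00646) and Spry2 (-0.84 ± 0.23, adjusted p = 0.00973) were among them. Mesoderm markers Wnt3 (2.58 ± 0.31, adjusted p = 2.48e-07) and Lhx1 (1.33 ± 0.26, adjusted p = 0.000372) were higher, 2 of 4 (also 2 adjusted over the list alone; camera adjusted p = 0.0452, adjusted p = 0.407 with an estimated correlation). The G1/S list held 3 lower of 25, the same number adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.411 with an estimated correlation). Mcm5 stood at -1.07 ± 0.18, adjusted p = 4.14e-05. SWI/SNF subunits held 2 higher, such as Arid1b (0.71 ± 0.17, adjusted p = 0.00312), and 6 lower of 27, such as Smarcc2 (-0.66 ± 0.16, adjusted p = 0.0035), or 6 and 7 adjusted over the list alone. The amino acid and unfolded protein list held Phgdh, a serine synthesis gene, higher (1.35 ± 0.25, adjusted p = 0.000186) and 3 of 12 lower (1 and 6 adjusted over the list alone). Oas1a, an antiviral enzyme gene, was among 3 interferon genes that were higher of 10 (1.82 ± 0.21, adjusted p = 1.5e-07; 3 higher and 1 lower adjusted over the list alone). Endoderm markers held 2 higher of 8 (2 adjusted over the list alone), while the neural list held 1 lower of 4 (2 higher and 1 lower adjusted over the list alone) and the fibroblast list Tagln lower (-0.66 ± 0.17, adjusted p = 0.00706) of 6, also adjusted over the list alone. Credited with the features nested in them, Tagln was higher instead (1.53 ± 0.29, adjusted p = 0.00135) and Bcl7c, the other higher SWI/SNF subunit, lower (-0.54 ± 0.17, adjusted p = 0.0274). Without MD09 replicate 2 the lists held 3 SWI/SNF subunits and 1 amino acid response gene lower, and 1 interferon and 0 endoderm genes higher. DESeq2 gave the same 1, 1 and 0 for the last 3 lists. No endoderm gene was higher without A04 replicate 1 and no neural gene lower without A10 replicate 1. Without A04 replicate 2, 5 genes each of G1/S and the amino acid response were lower. With each clone left out in turn, between 1902 and 3149 features differed.

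At 90 min the MD libraries held fewer counts and a larger share of mitochondrially encoded reads than R42A libraries, as the plot of counts per library shows. The feature CT010467.2 held 61437 and 148248 counts in the MD09 libraries, 598 and 661 in the MD30 libraries and 610 to 716 in all others. Smarce1 stood at 32.5 ± 5.01 CPM in MD and 37.1 ± 2.1 CPM in R42A cells (log2 -0.18 ± 0.20, adjusted p = 0.513). Of 77 ribosomal protein genes 36 were higher and 3 lower in MD (39 and 3 adjusted over the list alone; camera adjusted p = 1.46e-06, adjusted p = 0.759 with an estimated correlation). Rpl27a (1.62 ± 0.17, adjusted p = 9.36e-09), Rpl38 (1.72 ± 0.18, adjusted p = 9.36e-09) and Rpl26 (1.56 ± 0.19, adjusted p = 7.07e-08) were among them. Mitochondrially encoded features were higher too, 11 against 2 lower of 19, the same numbers adjusted over the list alone (camera adjusted p = 4.11e-05, adjusted p = 0.759 with an estimated correlation). The features mt-Ta (1.89 ± 0.27, adjusted p = 1.73e-06) and mt-Cytb (1.87 ± 0.27, adjusted p = 2.28e-05) were among them. Genes of G1/S, a list that did not pass the set test, held 13 lower and 1 higher of 25 (14 and 1 adjusted over the list alone; camera adjusted p = 0.155). Ccnd1 stood at -1.45 ± 0.24, adjusted p = 1.66e-05.

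A total of 9003 features differed, 3736 higher and 5267 lower, around a median of -0.13 over all tested features. DESeq2 put 3785 higher and 3406 lower, and without replicate 1 of the MD 90 min libraries, a fit chosen after the data were seen, 6598 features differed. The named decreases had 0 counts in MD and included Phf2os1 (at least 16.4-fold lower), the sulfite oxidase gene Suox (at least 8.1-fold) and Hoxaas2 (at least 6.91-fold), with adjusted p from 1.43e-08 to 1.42e-05. The named increases varied widely between the MD clones: Apoc3 (24.6 ± 33.7 against 0.0914 ± 0.129 CPM; 306-fold, interval 53.6 to 12194, adjusted p = 0.000687), Tex55 (58.7-fold, interval 19.1 to 293, adjusted p = 1.99e-06), Pvalb (31.1 ± 42 against 0.468 ± 0.113 CPM; 6.04 ± 1.09, adjusted p = 0.000645), Olfr739 (5.38 ± 0.78, adjusted p = 6.89e-05), Olfr1395 (5.53 ± 1.04, adjusted p = 0.00095) and Tg (5.43 ± 0.98, adjusted p = 0.000806). The call of Apoc3 was lost without MD09 replicate 2 (adjusted p = 0.473), that of Olfr1395 without MD09 replicate 1 (adjusted p = 0.412) and that of Tg without MD09 replicate 1 (adjusted p = 0.185). Without both replicate 1 libraries of MD at 90 min, Olfr1395 stood at -0.25, adjusted p = 0.931.

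Immediate early genes held 3 higher, with the phosphatase gene Dusp5 at 2.29 ± 0.22, adjusted p = 1.22e-09, and 9 lower of 25, the same adjusted over the list alone, with Maff at -1.72 ± 0.18, adjusted p = 6.46e-09 and Egr2 lower (15.5-fold, interval 4.19 to 130, adjusted p = 2.79e-06). Pluripotency genes held 6 lower, such as Esrrb (-1.19 ± 0.18, adjusted p = 3.28e-06) and Klf5 (6.42 and 6.36 against 27.8 and 23.7 CPM, adjusted p = 1.04e-05), and 3 higher of 29, 5 and 3 adjusted over the list alone. SWI/SNF subunits held 9 lower, such as Smarcd3 (-1.74 ± 0.28, adjusted p = 7.75e-06) and Actl6a (-1.14 ± 0.19, adjusted p = 1.22e-05), and 3 higher of 27, 10 and 3 adjusted over the list alone. Without MD09 replicate 1 the ribosomal list held 23 higher and the G1/S list 6 lower, and the latter 7 without MD09 replicate 2, 8 without A10 or MD30 replicate 1 and 6 with DESeq2, which put 5 SWI/SNF subunits lower. Pluripotency genes held 1 higher without MD30 replicate 1 and 5 without A10 replicate 1, and no mitochondrially encoded feature was lower without replicate 1 of MD09 or MD30 or with DESeq2. Omission of clone MD09 left 4674 features, and of MD30 6755.

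At 180 min Smarce1 stood at 21.5 ± 5.86 CPM in MD and 34.2 ± 0.27 CPM in R42A cells, and was lower (log2 -0.67 ± 0.18, adjusted p = 0.0102). This call ended without replicate 2 (-0.47) or clone A04, A10 or MD30 (-0.38 without MD30; adjusted p from 0.0554 to 0.34). Lgi1 was higher in MD (85.1 ± 0.715 against 8.32 ± 0.33 CPM; 3.35 ± 0.24, adjusted p = 2.48e-11) and Mras lower (17 ± 3.7 against 131 ± 10.6 CPM; -2.95 ± 0.30, adjusted p = 1.45e-06), as was Nkx6-3 (11.3 ± 1.01 against 74.6 ± 26.5 CPM; -2.71 ± 0.45, adjusted p = 0.00137). Grhl2 (1.55 ± 0.16, adjusted p = 3.49e-08) and the DNA methyltransferase gene Dnmt3b (1.36 ± 0.25, adjusted p = 0.000221) led 3 formative and primed pluripotency genes that were higher, with none lower, of 13 (also 3 adjusted over the list alone; camera adjusted p = 0.0987). Imprinted genes held 5 higher and none lower of 17, also 5 adjusted over the list alone (camera adjusted p = 0.0987). Peg3 (0.97 ± 0.22, adjusted p = 0.00291), H19 (2.27 ± 0.57, adjusted p = 0.00581) and Grb10 (0.82 ± 0.19, adjusted p = 0.0026) were among them.

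Here 3344 features differed, 1564 higher and 1780 lower, against 1716 and 1581 with DESeq2's size factors. Increases were also found for Mir6381 (25.6-fold, interval 6.69 to 218) and Mir142b (3.45 ± 0.76). The X-linked deubiquitinase gene Usp26 (2.94 ± 0.43) and Ugt2b34 (15.7 ± 1.21 against 2.21 ± 0.431 CPM) followed, all with adjusted p from 1.11e-07 to 0.00597. Decreases were also named for Emp1 (17.4-fold, interval 5.7 to 86.9, lower), Ccl17 (-3.04 ± 0.42), Mkks (-2.67 ± 0.54) and Olfr1428 (-2.58 ± 0.56), with adjusted p from 4.36e-06 to 0.00274. Ribosomal protein genes held 7 higher and 1 lower of 77, the same adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.716 with an estimated correlation). Rpl38 stood at 0.89 ± 0.17, adjusted p = 0.000432. Wnt and Nodal targets held 2 higher of 13, also 2 adjusted over the list alone (camera adjusted p = 0.0413, adjusted p = 0.308 with an estimated correlation). The Wnt feedback gene Rnf43 stood at 0.92 ± 0.22, adjusted p = 0.00352, and 1 was called without A04 replicate 1 or 2, A10 replicate 1 or MD09 replicate 1. Pluripotency genes held 6 lower, led by Tet2 (-1.04 ± 0.20, adjusted p = 0.000448) and Tbx3 (-1.07 ± 0.21, adjusted p = 0.000607), and 2 higher of 29, 8 and 3 adjusted over the list alone. The counts with 1 clone omitted ran between 1365 and 2578.

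At 240 min Smarce1 stood at 21.4 ± 0.132 CPM in MD and 35.2 ± 1.48 CPM in R42A cells, and was lower (log2 -0.72 ± 0.19, adjusted p = 0.00957). Without clone A04, MD09 or MD30, or without either replicate number, this call ended (adjusted p from 0.0594 to 0.0962). Targets of Wnt and Nodal signalling held 6 of 13 higher in MD and none lower (7 adjusted over the list alone; camera adjusted p = 0.00313, adjusted p = 0.0613 with an estimated correlation). Znrf3, a feedback inhibitor of Wnt signalling (0.84 ± 0.18, adjusted p = 0.00221), was among them. The count was 2 without A04 replicate 2 or MD09 replicate 1 and 3 without A04 replicate 1 or A10 replicate 2 or with no filter. Pluripotency genes held 7 lower, such as Fgf4 (-1.56 ± 0.30, adjusted p = 0.000466), Tbx3 (-1.13 ± 0.22, adjusted p = 0.000717) and Zfp42 (-0.80 ± 0.17, adjusted p = 0.00117), and Dnmt3l higher (1.03 ± 0.20, adjusted p = 0.000449) of 29, the same adjusted over the list alone (camera adjusted p = 0.00318, adjusted p = 0.455 with an estimated correlation). Lgi1 was higher (76.5 ± 5.6 against 6.51 ± 1.6 CPM; 3.57 ± 0.26, adjusted p = 6.98e-11), and the tight junction gene Ildr1 lower (4.64 ± 0.67 against 26.6 ± 8.94 CPM; -2.50 ± 0.28, adjusted p = 8.19e-08). Rapgef3os1, which lies inside Rapgef3 on the other strand, was lower as well (36.6 ± 2.57 against 189 ± 51 CPM; -2.37 ± 0.23, adjusted p = 4.79e-08).

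The count was 2521 features, 1463 higher and 1058 lower, against 1386 and 1416 with no filter. Also named as higher were Mir6381 (45-fold, interval 7.67 to 1816), Ugt2b34 (3.22 ± 0.34), Prr33 (2.92 ± 0.46) and Mir142b (2.85 ± 0.71), and as lower Nkx6-3 (-2.81 ± 0.47), the myoblast fusion gene Mymx (-2.71 ± 0.46), Fam171b (-2.54 ± 0.70) and Slc6a7 (-2.47 ± 0.53), with adjusted p from 4.79e-08 to 0.0372. The call of Fam171b ended without A04 replicate 2, MD09 replicate 1 or 2, or MD30 replicate 1 (adjusted p from 0.0503 to 0.0581). FGF-ERK feedback genes held 3 lower of 11, also 3 adjusted over the list alone (camera adjusted p = 0.0336, adjusted p = 0.455 with an estimated correlation), but 0 without MD09 replicate 1 or with DESeq2, and 1 without A04 replicate 1 or 2, A10 replicate 2 or MD30 replicate 1. Hoxc13, the called member of 4 measured Hox genes, was lower at every condition, from -2.89 in asynchronous cells to -1.82 at 240 min, and was also called adjusted over the list alone. Of 20 p53 targets 2 were lower, also 2 adjusted over the list alone, with Gdf15 at -1.35 ± 0.20, adjusted p = 1.42e-05 (1 without A10 replicate 1). Omitting single clones gave between 1114 and 1808 features.

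**Figure D2:**
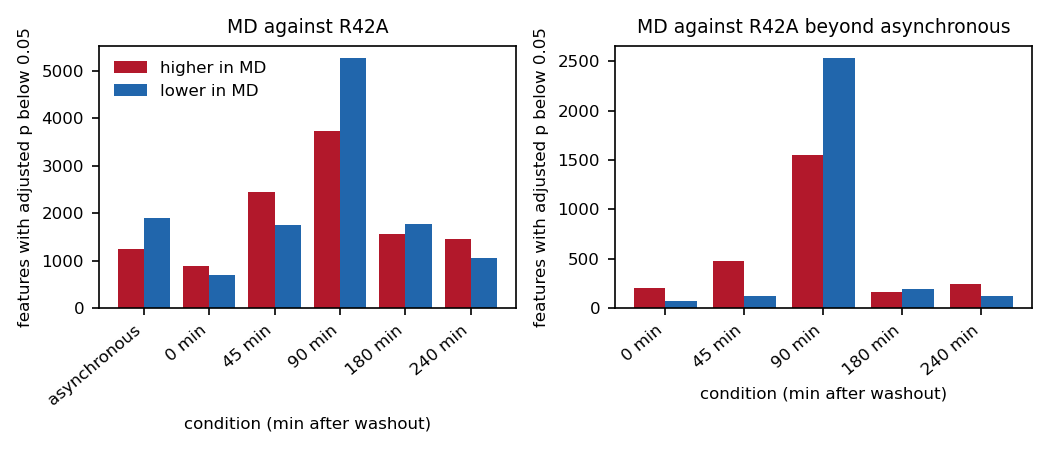
Number of features called higher (red) or lower (blue) in MD than in R42A at each condition (left), and called for a difference beyond that in asynchronous cells (right). The 90 min bars stand above all others, with 9003 features on the left and 4080 on the right.

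**Figure D3:**
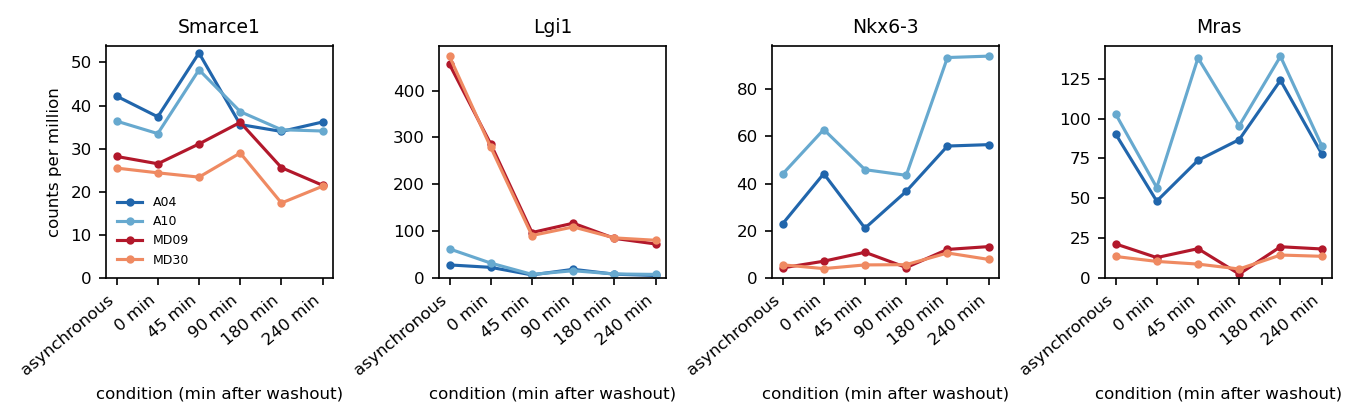
CPM of Smarce1, Lgi1, Nkx6-3 and Mras in each clone by condition, each point the sum of 2 libraries. The MD clones lie above the R42A clones for Lgi1 and below them for Nkx6-3 and Mras at every condition.

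The time comparisons asked how shares of counts changed on entry into mitosis and after release, first within R42A cells, each clone compared with itself. Absolute change was not measured, so rises and falls are of shares. The 0 min libraries, the baseline of later times, stood apart in low totals and high mitochondrial shares. At 0 min against asynchronous cells, heat shock genes held 4 of 11 that rose and none that fell (also 4 adjusted over the list alone; camera adjusted p = 0.0215, adjusted p = 0.767 with an estimated correlation). The chaperone gene Dnajb1 (2.07 ± 0.21, adjusted p = 6.99e-11) was among them. The count was 7 without asynchronous A10 replicate 1 and 8 with DESeq2's size factors. Ribosomal protein genes rose, 48 against 1 that fell of 77 (52 and 1 adjusted over the list alone; camera adjusted p = 4.77e-08, adjusted p = 0.767 with an estimated correlation). Rps3 (1.04 ± 0.17, adjusted p = 1.22e-06) was among them. Of 29 pluripotency genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; camera adjusted p = 0.0215, adjusted p = 0.902 with an estimated correlation). The RNA-binding factor gene Lin28a stood at 1.60 ± 0.18, adjusted p = 1.26e-09, Nanog at 1.14 ± 0.21, adjusted p = 2.11e-05 and Pou5f1 at 0.94 ± 0.18, adjusted p = 2.59e-05. Endoderm markers held 7 that rose and 1 that fell of 8, the same adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.496 with an estimated correlation). The basement membrane genes Lama1 (1.71 ± 0.24, adjusted p = 1.36e-07) and Col4a2 (1.54 ± 0.25, adjusted p = 2.24e-06) were among them.

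At 0 min 11036 features differed, 4548 higher and 6488 lower, and 7533 and 7857 without clone A10 or A04. The named increases included Gprc6a, a receptor gene (4.11 ± 0.37), Myt1 (22-fold, interval 5.41 to 193) and Olfr113 (42-fold, interval 6.76 to 1737), with adjusted p from 2.95e-12 to 2.5e-05. The named decreases included the kinase subunit gene Pik3r3 (at least 18.2-fold), Insm2 (at least 17.2-fold) and Orm3 (at least 7.33-fold), with adjusted p from 1.86e-09 to 1.51e-05.

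At 45 min against 0 min, immediate early genes rose in R42A cells, 13 against 2 that fell of 25 (14 and 2 adjusted over the list alone; camera adjusted p = 0.0456, adjusted p = 0.619 with an estimated correlation), with the transcription factor genes Maff (1.47 ± 0.18, adjusted p = 4.89e-09), Fosl1 (1.24 ± 0.15, adjusted p = 6.84e-09) and Egr2 (1.79 ± 0.25, adjusted p = 1.03e-07). Targets of p53 rose too, 11 against 1 of 20 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0456, adjusted p = 0.619 with an estimated correlation). Gdf15 (1.83 ± 0.22, adjusted p = 2.18e-09) and the apoptosis gene Bax (1.72 ± 0.25, adjusted p = 3.01e-07) were among them. Ribosomal protein genes fell, 55 against 4 that rose of 77 (56 and 5 adjusted over the list alone; camera adjusted p = 1.11e-09, adjusted p = 0.619 with an estimated correlation). Rpl4 (-1.21 ± 0.15, adjusted p = 8.28e-09) was among them. Mitochondrially encoded features fell, 15 of 19, the same adjusted over the list alone (camera adjusted p = 2.08e-07, adjusted p = 0.619 with an estimated correlation). They held 0.55 to 0.634% of counts at 0 min, 0.193 to 0.221% at 45 min and 0.245 to 0.291% in asynchronous libraries. Of 4 measured replication-dependent histone genes 2 rose, also 2 adjusted over the list alone, and 0 without 0 min A04 replicate 1 or with DESeq2.

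The total at 45 min was 11140 features, 5976 higher and 5164 lower, against 5572 and 5626 with DESeq2's size factors and 4643 and 4900 with DESeq2. Named increases included the homeobox gene Otp (at least 7.05-fold), the apolipoprotein gene Apoa5 (at least 6.26-fold) and Dlx6os1 (at least 5.92-fold), with adjusted p from 9.82e-06 to 0.000138. Named decreases included Olfr395 (-4.03 ± 1.01), Phf11b (-3.84 ± 0.77) and Lrtm1 (15.6-fold, interval 4.47 to 83.7), with adjusted p from 6e-05 to 0.00262. Leaving out clone A04 gave 7458 features and A10 7469.

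At 90 min in R42A cells pluripotency genes held lower shares than at 0 min, 16 against 1 that rose of 29 (17 and 1 adjusted over the list alone; camera adjusted p = 2.93e-05, adjusted p = 0.426 with an estimated correlation). Lin28a stood at -1.28 ± 0.17, adjusted p = 7.94e-08 and Klf2 at -1.80 ± 0.29, adjusted p = 2.59e-06. Genes of G2/M held 12 that fell and 3 that rose of 28 (13 and 4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.249 with an estimated correlation). The proliferation marker Mki67 (-1.43 ± 0.17, adjusted p = 4.82e-09) and Cdc20, an activator of the anaphase-promoting complex (-1.66 ± 0.20, adjusted p = 7.86e-09), were among them. Ribosomal protein genes fell, 64 of 77 with none higher (65 adjusted over the list alone; camera adjusted p = 3.61e-29, adjusted p = 0.098 with an estimated correlation). Heat shock genes fell, 6 of 11, the same adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.426 with an estimated correlation), with Dnajb1 at -1.67 ± 0.20, adjusted p = 2.74e-09.

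Here 9700 features differed, 5611 higher and 4089 lower, and 6127 without clone A10. Those named as higher included Scgb1b30 (22.9-fold, interval 7.73 to 112), Mir181a-2 (at least 7.42-fold) and Otp (at least 6.75-fold), with adjusted p from 1.75e-09 to 2.75e-05. Those named as lower included Rapgef4os2 (-4.82 ± 0.40), Nxpe2 (-3.89 ± 0.38) and Olfr978 (45.2-fold, interval 14.5 to 227), with adjusted p from 3.47e-13 to 1.41e-10.

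At 180 min against 0 min in R42A cells, mesoderm markers held 3 that rose and 1 that fell of 4, the same adjusted over the list alone (camera adjusted p = 0.0383, adjusted p = 0.312 with an estimated correlation): Lhx1 (4.42 ± 0.34, adjusted p = 2.94e-14), Eomes (2.23 ± 0.26, adjusted p = 2.24e-09) and Wnt3 (2.26 ± 0.38, adjusted p = 3.25e-06) rose. Pluripotency genes fell, 19 against 1 of 29 (20 and 1 adjusted over the list alone; camera adjusted p = 4.33e-06, adjusted p = 0.317 with an estimated correlation), led by Lin28a (-2.15 ± 0.18, adjusted p = 3.18e-13). G2/M genes fell, 14 against 5 of 28 (14 and 6 adjusted over the list alone; camera adjusted p = 0.0302, adjusted p = 0.312 with an estimated correlation). The kinesin gene Kif23 stood at -2.03 ± 0.24, adjusted p = 2.52e-09. Ribosomal protein genes held 65 that fell and 2 that rose (67 and 2 adjusted over the list alone; camera adjusted p = 3.57e-22, adjusted p = 0.235 with an estimated correlation). Ribosome biogenesis genes held 9 that fell and 2 that rose of 20, the same adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.367 with an estimated correlation). The nucleolin gene Ncl stood at -1.27 ± 0.14, adjusted p = 4.37e-10. Mitochondrially encoded features fell too (15 of 19, 17 adjusted over the list alone; camera adjusted p = 4.02e-08, adjusted p = 0.317 with an estimated correlation). They held 0.138 to 0.197% of counts, against the high share at 0 min. Of 2 measured two-cell-like genes 1 rose, also adjusted over the list alone, a call lost without any 1 of the 0 min libraries or replicate 2 of A04 or A10 at 180 min.

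The 180 min total was 11890 features, 6916 higher and 4974 lower, around a median of 0.15 over all tested features, and 8308 without clone A10. Named increases included the pancreatic homeobox gene Pdx1 (at least 13.5-fold), the nuclear body gene Sp110 (at least 25.2-fold) and Ptprtos (at least 23.2-fold), with adjusted p from 8.19e-12 to 4.01e-07. Named decreases included the transcription factor gene Osr1 (49.3-fold, interval 15.8 to 249), Barhl2 (47.6-fold, interval 12 to 413) and Apol10a (52.8-fold, interval 8.13 to 2224), with adjusted p from 9.75e-08 to 2.58e-05.

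At 240 min in R42A cells the mesoderm list again held Lhx1 (5.08 ± 0.33, adjusted p = 1.03e-16), Eomes (2.01 ± 0.27, adjusted p = 6.18e-08) and Wnt3 (1.86 ± 0.40, adjusted p = 0.000187) higher and 1 lower of 4, the same adjusted over the list alone (camera adjusted p = 0.0436, adjusted p = 0.409 with an estimated correlation). Pluripotency genes held 19 lower and none higher (19 and 1 adjusted over the list alone; camera adjusted p = 4.88e-05, adjusted p = 0.514 with an estimated correlation). Ribosomal protein genes held 59 lower and 3 higher (61 and 3 adjusted over the list alone; camera adjusted p = 1.95e-10, adjusted p = 0.409 with an estimated correlation), Rps28 among the latter (1.32 ± 0.16, adjusted p = 2.51e-09). In all 10725 features differed, 5968 higher and 4757 lower, and 6625 without clone A10. The neurokinin receptor gene Tacr3 (-4.33 ± 0.44), Vmn2r32 (-4.33 ± 0.50) and Osr1 (36.6-fold, interval 11.7 to 184) were among those named as lower, with adjusted p from 6.5e-11 to 5.33e-05.

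**Figure D4:**
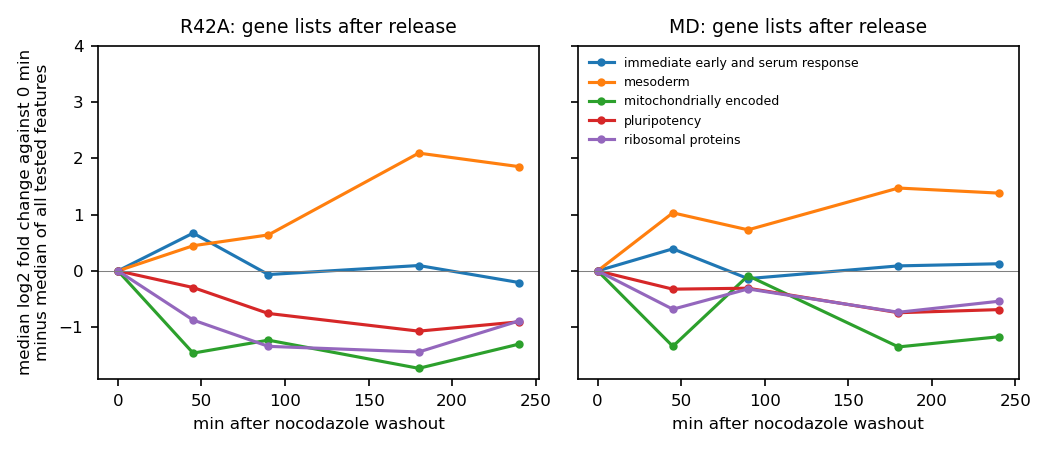
Median log2 fold change against 0 min of 5 gene lists, less the median of all tested features, by minutes after nocodazole washout in R42A (left) and MD cells (right). At 180 min the pluripotency list stood at -1.07 in R42A and -0.74 in MD cells.

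The same time comparisons were made in MD cells. At 0 min against asynchronous cells no list passed the set test. Rgs10, a regulator of G-protein signalling, rose (65.9 ± 6 against 2.03 ± 0.0413 CPM; 5.00 ± 0.28, adjusted p = 5.61e-17), as did Pgm5, a phosphoglucomutase-like gene (68.7 ± 0.602 against 2.02 ± 0.368 CPM; 5.08 ± 0.88, adjusted p = 0.000795). Ribosomal protein genes held 11 that rose and 2 that fell of 77, the same adjusted over the list alone (camera adjusted p = 0.108; 21 rose with DESeq2's size factors), and endoderm markers 6 and 1 of 8, the same adjusted over the list alone (camera adjusted p = 0.0663). A total of 10170 features differed, 4286 higher and 5884 lower, against 5099 and 4994 with DESeq2's size factors and 4279 and 4225 with DESeq2, and 6454 without clone MD30. Further named increases included Acod1 (at least 15.7-fold) and named decreases Nkx6-2 (37-fold, interval 6.39 to 1483), Pik3r3 (33.4-fold, interval 5.75 to 1342) and Tmem210 (18.2-fold, interval 4.82 to 154), with adjusted p from 1.18e-07 to 3.34e-05.

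At 45 min in MD cells mitochondrially encoded features fell, 15 of 19, the same adjusted over the list alone (camera adjusted p = 8.65e-09, adjusted p = 0.717 with an estimated correlation). They held 0.427 to 0.657% of counts at 0 min, 0.188 to 0.284% at 45 min and 0.287 to 0.31% in asynchronous libraries. The feature mt-Rnr2 stood at -1.51 ± 0.16, adjusted p = 1.12e-09. Ribosomal protein genes fell, 44 against 4 (47 and 4 adjusted over the list alone; camera adjusted p = 7.52e-06, adjusted p = 0.717 with an estimated correlation). Rpl4 stood at -0.99 ± 0.15, adjusted p = 1.13e-06 and Rps10 rose (1.83 ± 0.29, adjusted p = 1.73e-06). Immediate early genes held 11 that rose and 1 that fell of 25, the same adjusted over the list alone (camera adjusted p = 0.217). Those that rose were 6 without MD30 0 min replicate 1, 7 without MD09 45 min replicate 1, 6 with DESeq2's size factors and 5 with DESeq2. In total 9595 features differed, 5515 higher and 4080 lower, against 4460 and 5032 with DESeq2's size factors and 3543 and 4263 with DESeq2, and without clone MD09 5333 differed. Named increases included the kinase gene Camkk1 (19.5-fold, interval 6.54 to 95.7), Odf3l2 (16.7-fold, interval 4.47 to 140) and Otp (16.9-fold, interval 2.87 to 683), with adjusted p from 1.22e-08 to 0.000503.

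At 90 min, in the libraries with low totals and high mitochondrial shares described above, pluripotency genes held 9 lower than at 0 min and none higher of 29, the same adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.717 with an estimated correlation). Sall4 (-1.30 ± 0.20, adjusted p = 5.23e-06) and Pou5f1 (-1.09 ± 0.22, adjusted p = 0.000168) were among them, but counts of features nested in Pou5f1 rose (1.25 ± 0.43, adjusted p = 0.0419). Ribosomal protein genes held 21 lower and 1 higher (25 and 1 adjusted over the list alone; camera adjusted p = 0.00421, adjusted p = 0.717 with an estimated correlation). Rps12 stood at -0.96 ± 0.22, adjusted p = 0.00123. The number lower was 12 without MD09 replicate 2 or MD30 replicate 1 at 0 min, 11 without MD09 and 13 without MD30 replicate 2 at 90 min, and 12 with no filter or DESeq2. The count was 6073 features, 3163 higher and 2910 lower, 5528 without replicate 1 at 90 min and 1404 without clone MD09. Increases named included Vmn2r13 (at least 25.2-fold), Apoc3 (59.3-fold, interval 16 to 496) and Mocos (4.50 ± 1.11), with adjusted p from 2.38e-06 to 0.0131. Apoc3 stood at -0.16, adjusted p = 0.965 when MD09 90 min replicate 2 was left out. Decreases named included the snoRNA host gene Snhg3 (at least 11.4-fold), Mgl2 (at least 10.6-fold) and Olfr1215 (at least 8.35-fold), with adjusted p from 7.77e-06 to 8.6e-05.

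At 180 min in MD cells mesoderm markers Lhx1 (4.57 ± 0.28, adjusted p = 2.39e-17), Eomes (from 7.11 and 5.47 to 27.7 and 22.8 CPM, adjusted p = 3.98e-08) and Wnt3 (1.16 ± 0.28, adjusted p = 0.000805) rose and Mixl1 fell (-1.37 ± 0.34, adjusted p = 0.000867), each of the 4, also adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.434 with an estimated correlation). Pluripotency genes fell, 17 against 2 (17 and 2 adjusted over the list alone; camera adjusted p = 0.000319, adjusted p = 0.434 with an estimated correlation), with Tet2 at -1.50 ± 0.18, adjusted p = 5.84e-09 and Tfcp2l1 at -1.55 ± 0.20, adjusted p = 2.9e-08. Ribosomal protein genes fell too, 47 against 4 (48 and 4 adjusted over the list alone; camera adjusted p = 2.34e-07, adjusted p = 0.434 with an estimated correlation), as did 14 mitochondrially encoded features (15 adjusted over the list alone; camera adjusted p = 3.19e-07, adjusted p = 0.434 with an estimated correlation). The latter held 0.202 to 0.222% of counts, against the high share at 0 min. In total 10663 features differed, 6201 higher and 4462 lower, around a median of 0.11, and 6624 without clone MD09. The interleukin gene Il1b (37.9-fold, interval 10.3 to 315), H2bc1 (at least 7.34-fold) and Nudt10 (at least 5.54-fold) were among those named as higher, with adjusted p from 4.33e-10 to 6.8e-05.

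At 240 min in MD cells Slc5a12, a lactate transporter gene, was far above its 0 min level (206 ± 5.35 against 4.57 ± 2.25 CPM; 5.51 ± 0.44, adjusted p = 8.67e-08). The mesoderm list held 3 higher and 1 lower of 4, the same adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.454 with an estimated correlation). Lhx1 stood at 5.10 ± 0.27, adjusted p = 2.78e-19. Pluripotency genes held 16 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.000373, adjusted p = 0.793 with an estimated correlation). The count was 10278 features, 5893 higher and 4385 lower, and 6560 without clone MD09. Mrgprg (at least 8.5-fold), Nudt10 (at least 8.2-fold) and Timp4 (at least 7.01-fold) were among those named as higher, and Snhg3 (30.6-fold, interval 9.75 to 154), Cldn34a (-4.59 ± 0.51) and Mep1a (22.4-fold, interval 5.43 to 197) as lower, all with adjusted p from 7.26e-10 to 2.58e-05.

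The interaction comparisons asked whether the difference between MD and R42A cells at each time after release differed from that in asynchronous cells, with levels below given per clone, A04 and A10 before MD09 and MD30. At 0 min large gains of that difference were found in Acads, a gene of fatty acid oxidation (2.88 ± 0.57), Rbbp8nl (3.08 ± 0.58), Begain (3.07 ± 0.42), Caly (3.36 ± 0.69) and Prph2 (2.81 ± 0.59). The largest losses were in the urokinase receptor gene Plaur (-2.48 ± 0.50), Gprc6a (-2.51 ± 0.51), the peroxidase gene Lpo (-2.49 ± 0.58), Id1 (-2.87 ± 0.70), Aspa (-2.38 ± 0.54) and Taf7 (-2.96 ± 0.70), with adjusted p from 4.43e-05 to 0.0263. Plaur stood at 1.65 and 2.33 against 4.56 and 3.82 CPM in asynchronous clones, and at 22.1 and 24.4 against 8.53 and 8.95 CPM at 0 min. Art5, with 1 count in R42A cells at 0 min, stood there at 0 and 0.567 against 2.84 and 3.48 CPM (adjusted p = 0.0426). Among list members Zfp42 (-0.88 ± 0.23, adjusted p = 0.0431), Peg10 (-1.17 ± 0.30, adjusted p = 0.0382) and Jun (-1.97 ± 0.52, adjusted p = 0.0469) had lower differences, and no list passed the set test. In all 270 features passed, 204 higher and 66 lower, and between 13 and 173 with 1 clone left out. It was 151 with the 48 libraries fitted singly and 149 without a clone term. The count was 99 without A10 asynchronous replicate 1, 128 without A04 asynchronous replicate 1, 162 without A10 0 min replicate 1 and 473 without A10 asynchronous replicate 2. Without replicate 1 or 2 of all clones it was 9 and 179. Plaur, Gprc6a, Rbbp8nl and Begain passed with each library left out. Each of the 16 libraries of these conditions ended at least 1 of the other calls when left out (adjusted p from 0.0503 to 0.308).

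At 45 min the immediate early genes Egr1 (-1.77 ± 0.36, adjusted p = 0.00221) and Ccn1 (-1.68 ± 0.43, adjusted p = 0.0209) had lower differences than in asynchronous cells, and Wnt3, a signalling gene of early mesoderm, a higher one (3.09 ± 0.43, adjusted p = 1.37e-05). Klhl30 (3.62 ± 0.43), at 13 and 10.2 against 3.14 and 1.17 CPM in asynchronous and 7.18 and 5.83 against 13.7 and 16.8 CPM at 45 min, Zfp947 (3.80 ± 0.71), Hotair (3.17 ± 0.60) and Selp (3.14 ± 0.77) had large gains. Ap1s1 (-2.09 ± 0.54), Twistnb (-2.33 ± 0.63), the growth factor gene Hbegf (-2.65 ± 0.73), Ugt2b34 (-2.66 ± 0.74) and Tmprss13 (-2.73 ± 0.77) had large losses, with adjusted p from 1.06e-06 to 0.042. With a group at 1 to 3 counts, Ccdc201 fell from 14.1 and 9.03 to 0 and 0.376 CPM in R42A clones (adjusted p = 0.0261). Tfap2c (-1.51 ± 0.30, adjusted p = 0.00155), Nr5a2 (-0.93 ± 0.24, adjusted p = 0.0205) and Grb10 (-0.92 ± 0.26, adjusted p = 0.0377) had lower differences as well, and no list passed the set test. The total was 593, 475 higher and 118 lower, against 224 and 98 with DESeq2, 425 and 231 with no filter and 453 and 282 without the 90 min libraries. It was 356 with libraries fitted singly and 342 without a clone term. It was between 147 and 356 with 1 clone left out, 313 without A10 asynchronous replicate 1, 346 without MD09 45 min replicate 2, and 332 and 187 without replicate 1 or 2 of all clones. Egr1, Wnt3, Klhl30, Zfp947, Hotair and Tfap2c passed with each library left out. Each of the 16 libraries of these conditions ended at least 1 of the other calls when left out (adjusted p from 0.051 to 0.387).

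At 90 min, where the MD libraries had low totals and high mitochondrial shares, 14 of 77 ribosomal protein genes had higher differences and none lower (15 adjusted over the list alone; camera adjusted p = 1.74e-06, adjusted p = 0.724 with an estimated correlation), such as Rpl27a (1.61 ± 0.24, adjusted p = 1.26e-05). Higher differences were also found for 10 of 19 mitochondrially encoded features (10 adjusted over the list alone; camera adjusted p = 1.74e-06, adjusted p = 0.724 with an estimated correlation). The feature mt-Nd5 stood at 4.53 ± 1.15, adjusted p = 0.0222. Immediate early genes held 7 lower and 2 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.565), with the phosphatase gene Dusp5 higher (2.13 ± 0.32, adjusted p = 1.2e-05) and Ccn1 lower (-2.32 ± 0.48, adjusted p = 0.00072). Grb10 (-1.71 ± 0.24, adjusted p = 3.78e-06) and Esrrb (-0.84 ± 0.23, adjusted p = 0.00788) had lower differences and Nodal, a TGF-beta family ligand, a higher one (1.36 ± 0.27, adjusted p = 0.000495). Clec3a (5.93 ± 1.05, adjusted p = 0.00163), Olfr739 (5.75 ± 1.23, adjusted p = 0.00101) and Olfr1395 (5.03 ± 1.75, adjusted p = 0.0479) also gained. Bbox1 stood at 0.366 and 0.194 against 2.96 and 2.83 CPM at 90 min (adjusted p = 0.00135), and Aga at 0 and 0.294 CPM in asynchronous and 5.43 and 6.36 CPM in 90 min MD clones (adjusted p = 0.015). Phf2os1, Clpsl2, Suox, Rskr, Zfp658 and Mir1970 lost all counts in MD cells at 90 min (adjusted p from 8.97e-06 to 0.0162). The total was 4080, 1548 higher and 2532 lower around a median of -0.12, against 1943 and 1973 with DESeq2's size factors and 1473 and 1356 with DESeq2. It was between 1355 and 3124 with 1 clone left out, 2101 without MD09 90 min replicate 1, and 2117 without replicate 1 of all clones. Without MD09 90 min replicate 1 the ribosomal list held 6 higher (9 without asynchronous A04 replicate 2) and the immediate early list 3 lower (4 without MD30 90 min replicate 1 or with DESeq2). Esrrb lost its call without asynchronous MD09 replicate 1 (adjusted p = 0.142) and Nodal without 90 min MD09 replicate 1 (adjusted p = 0.0611). At least 1 of the Clpsl2 and Olfr1395 calls was lost without replicate 2 of asynchronous A04, MD09 or MD30, replicate 2 of 90 min A04, A10 or MD09, or replicate 1 of 90 min MD09 or MD30 (adjusted p from 0.0561 to 0.871), Olfr1395 with a negative value (-0.64, adjusted p = 0.867) without replicate 1 of both MD clones at 90 min.

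At 180 min Klhl30 stood at 13.7 and 10.1 against 13.4 and 16 CPM (adjusted p = 0.00016), and its difference gained most. Next came Slc35b1 (2.64 ± 0.69), Macrod2os1 (2.41 ± 0.51) and Faah (2.29 ± 0.49). The potassium channel gene Kcnc1 (2.13 ± 0.41) and Dok7 (2.08 ± 0.44) followed, with adjusted p from 0.00016 to 0.0334. Losses were named for Plaur (-2.84 ± 0.49), the Wnt ligand gene Wnt7b (-2.52 ± 0.54) and Nwd1 (-2.36 ± 0.30). Tmprss13 (-3.07 ± 0.83) and Zfp709 (-2.57 ± 0.65) followed, with adjusted p from 5.5e-06 to 0.0442. Grb10 had a lower difference (-1.72 ± 0.22, adjusted p = 5.5e-06), at 28.1 and 33.2 against 216 and 147 CPM in asynchronous and 34.2 and 42.8 against 72 and 63.6 CPM in 180 min clones. No list passed the set test. The total was 353, 161 higher and 192 lower. It was 541 with no filter, 585 without the 90 min libraries and 191 without a clone term. Counts ran between 47 and 459 with 1 clone left out, 234 without A10 asynchronous replicate 1, 565 without its replicate 2. Without replicate 1 or 2 of all clones they were 120 and 194. Faah lost its call without asynchronous A10 replicate 1 (adjusted p = 0.147), and at least 1 of Slc35b1, Tmprss13 and Zfp709 without any 1 of the asynchronous libraries, 180 min A04 replicate 2, or a 180 min library of A10 or MD09 (adjusted p from 0.0505 to 0.278).

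At 240 min Klhl30 (3.03 ± 0.43), Tmem269 (2.89 ± 0.67), Slc35b1 (2.78 ± 0.69), Enpp5 (2.72 ± 0.66), Faah (2.53 ± 0.49) and Dpysl4 (0.995 and 0.716 against 2.86 and 3.7 CPM) had the largest gains. Wnt7b (-2.76 ± 0.54), the secreted matrix gene Spp1 (-2.67 ± 0.54), Plaur (-2.63 ± 0.49), Nwd1 (-2.57 ± 0.31) and Cdc42ep3 (-2.08 ± 0.56) had large losses, with adjusted p from 1.14e-06 to 0.0404. Nodal had a higher (0.99 ± 0.26, adjusted p = 0.0307) and Ccn1 (-1.71 ± 0.42, adjusted p = 0.0206) and Grb10 (-1.27 ± 0.23, adjusted p = 0.00113) lower differences, and no list passed the set test. The total was 362, 242 higher and 120 lower, against 238 and 219 with no filter. It was 240 with libraries fitted singly and 197 without a clone term. Counts ran between 42 and 399 with 1 clone left out, 211 without A10 asynchronous replicate 1, 239 without A04 asynchronous replicate 1, 550 without A10 asynchronous replicate 2, and 69 without replicate 1 of all clones. Klhl30, Wnt7b, Spp1, Plaur and Nwd1 passed with each library left out. At least 1 of the other calls was lost without any 1 library of these conditions other than replicate 2 of A04 and asynchronous MD30 replicate 1 (adjusted p from 0.05 to 0.246).

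The last comparison asked whether genes switched on after release stood lower in MD cells. The 0 min difference was not subtracted, so whether they rose less was not tested. Over 7592 features called higher at 240 min than at 0 min in the mean of the genotypes, the median log2 difference between MD and R42A cells, less that of all tested features, was 0.08 at 45 min (SD over the 4 pairings of clones 0.03), -0.30 at 90 min (SD 0.06, from -0.34 to -0.22), -0.03 at 180 min (SD 0.02) and 0.02 at 240 min (SD 0.05). No test was planned for these values, and an exact test of 2 clones against 2 can give no p below 0.33. The 90 min value rests on the MD libraries with low totals, and was -0.17 without their replicate 1 and -0.48 without replicate 2 throughout. The 45 min value was 0.04 with no filter and 0.13 without replicate 2. With the features chosen at 90 min instead, the values were -0.14, -0.23, -0.11 and -0.05.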

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

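The tests of reads without strand and of a slower course, and the fits without single features or replicates, were chosen only after the result was seen.

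Most counts lay in features overlapped by a gene on the other strand (78.7%). Features wholly inside 1 protein-coding gene of the opposite strand (2881) held a median of 41 reads per kb, and Brip1os, for example, held 48505 counts against 225 in Brip1. Over 970 genes compared with the features nested in them, a gene's own density was a median 1.65% of that of its nested features. Counting without strand that sets reads in overlapping genes aside would favour features with no opposite-strand gene, yet these held 0.0168 times the density of nested ones (95% interval 0.0141 to 0.0199). Transcription of the nested features themselves would not follow the surrounding gene, yet those inside genes of expressed lists were 66 times denser than those inside genes of silent lists (interval 4.33 to 4785, 19 against 7 features). Reads credited to the strand opposite to the transcribed gene could give that ratio of 66, the 1.65% and the low density of features with no opposite-strand gene. They stay a candidate explanation, since the strand setting was not given in the sources used here.

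The MD libraries at 90 min stood apart, with 4080 features called by the interaction test. It called 270 at 0 min, 593 at 45 min, 353 at 180 min and 362 at 240 min. The 180 min count was 294 with the MD 180 min sums thinned to the MD 90 min depth. Thinning only removes information, so this cannot decide whether low depth had a part. Neither CT010467.2 with the mitochondrially encoded features (4057 without them) nor the replicate 1 libraries (2907 without them) can be the whole cause. A slower or stalled course cannot be told apart: each library correlated better with R42A at 90 than at 45 min, but both replicate 1 libraries correlated better with R42A at 0 min (MD09 0.802, MD30 0.817) than at 90 min (0.755 and 0.765), a lowest excess of -0.052. Low depth, another fault shared by these 4 libraries and another effect of the genotype at 90 min stay open too. The design cannot separate them.

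Differences between MD and R42A recurred from condition to condition: 213 features were higher and 150 lower in MD at each condition except 90 min, where 0.0189 and 0.0136 would be shared by independent lists. Differences between clones regardless of genotype would recur as strongly in other splits of the 4 clones, yet the median correlation over pairs of conditions was 0.635 for the genotypes and at most 0.258 for these splits. Lasting effects of degradation, and differences between the lines from their derivation, may both remain, and the design cannot tell them apart.

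With libraries as samples, the real split of the 8 libraries called most features of 35 at each condition. It called 3604 in asynchronous cells (highest other 1), 2163 at 0 min (5), and 4780, 5471, 4463 and 4451 at 45, 90, 180 and 240 min (each 0). Every other split mixed genotypes, which widens the spread within groups, so its low count cannot exclude chance. Libraries of a clone are not independent, so chance between clones stays open. The 4 clones allow 3 splits, too few for a share under 0.05. There the highest other was 0 by edgeR for genotypes and interactions, against the counts given above.

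Single libraries lay apart from the other 3 of their group for 3 of the 60 groups tested, and chance gives about 1 in 20: R42A 240 min A04 replicate 2 held 2623004 gene counts (others 2049967 to 2146400), R42A 0 min A04 replicate 1 held 0.634% mitochondrially encoded counts (others 0.55 to 0.556%), and MD asynchronous MD30 replicate 2 held 0.287% (others 0.308 to 0.31%).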

How the results depend on the processing

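Settings without the 90 min libraries, MD 90 min replicate 1 or CT010467.2 and mitochondrially encoded features were chosen after the data were seen. Over settings other than left-out libraries or clones, 179 main values stayed on their side of the threshold within 1.5 times or 1 SD, and 18 did not. The cause was not tested. The interaction counts at 0, 45 and 240 min (270, 593 and 362) fell to 151, 356 and 240 with the 48 libraries fitted singly, and without a clone term those at 0, 45, 180 and 240 min were 149, 342, 191 and 197. DESeq2 gave 322 at 45 min, and no filter 541 and no 90 min libraries 585 at 180 min. For activated features the median was 0.0406 at 45 min and -0.357 at 90 min with no filter, -0.17 at 90 min without MD 90 min replicate 1, and -0.136, -0.232, -0.113 and -0.0543 at 45, 90, 180 and 240 min with features chosen at 90 min.

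Replicate numbers did not pair the samples throughout: over 36 pairs of clones the correlation of same-numbered deviations ran from -0.164 to 0.877, 4 above 0.1. At 90 min it was 0.877 for the MD and 0.395 for the R42A clones, and at 45 min 0.291 for the R42A clones, so sums of these clones shared a replicate difference that the spread between them leaves out. With the replicate number as a replicate block, 165 features were called in the interaction at 0 min and 380 at 45 min, close to the 48 libraries without it.

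With libraries, replicate numbers or clones left out, a lone clone being assumed to vary like the other groups, MD against R42A counts ran from 1315 to 3313 (asynchronous), 571 to 1617 (0 min), 1764 to 4316 (45 min), 4674 to 9007 (90 min), 1365 to 3340 (180 min) and 1114 to 2440 (240 min). R42A time counts ran from 7533 to 10939, 7458 to 10854, 6127 to 9556, 8308 to 11727 and 6625 to 10518, and MD ones from 6454 to 9721, 5333 to 9511, 1404 to 6182, 6624 to 10359 and 6560 to 9893. Interaction counts ran from 9 to 473, 147 to 786, 1355 to 5021, 47 to 565 and 42 to 550, and the activated medians from 0.0603 to 0.13, -0.477 to -0.17, -0.0506 to 0.0256 and -0.0543 to 0.039.

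Named features, Smarce1 included, kept their direction and their side of the threshold in 11425 fits, lost their call in 1318, gained one in 5, changed sign in 5 and stood at 0 in 1. Olfr1395 at 90 min stood at -0.25 (MD against R42A) and -0.636 (interaction) without MD 90 min replicate 1, against up to 6.44 and 6.41 with other libraries left out. Smarce1 at 90 min ran from -0.358 to 0.00787, the latter without clone MD30. Apoc3 ran from 0 (without replicate 2) to 9.79 in MD against R42A at 90 min, and in MD at 90 against 0 min from -3.13 (without replicate 2) to 6.58, with -0.159 without MD09 90 min replicate 2. Some single library moved 188 of 302 gene list counts of 1 or 2 members and 64 of 294 counts of 3 or more by over 1.5 times. Depth limits the MD 90 min and the 0 min libraries most.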

Other observations

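The crediting of nested features to the surrounding gene and the choice of persistent features were made only after the data were seen. With the 2881 nested features so credited, 1726 surrounding genes could be tested. Grhl2, a transcription factor of epithelial genes, was then higher in MD at each condition, from 1.54 ± 0.25 at 0 min (adjusted p = 0.000137) to 2.85 ± 0.26 at 90 min (adjusted p = 5.37e-09), as was Tagln, an actin-binding gene of smooth muscle, from 1.13 ± 0.29 at 240 min (adjusted p = 0.0146) to 2.23 ± 0.30 at 90 min (adjusted p = 1.26e-05), while the feature named Tagln was lower at 45, 90 and 180 min. The trophoblast gene Gata3 (2.33 ± 0.44, adjusted p = 0.000657) and the Wnt feedback gene Axin2 (1.07 ± 0.27, adjusted p = 0.00724) were higher at 240 min. In R42A cells the mitotic kinase gene Plk1 was lower at 180 min than at 0 min (-1.68 ± 0.17, adjusted p = 2.99e-10), and so was Pou5f1 (-1.74 ± 0.43, adjusted p = 0.00471). At 90 min, however, Pou5f1 so counted was higher in MD than in R42A cells (2.87 ± 0.42, adjusted p = 9.04e-05) and than at 0 min in MD cells (1.25 ± 0.43, adjusted p = 0.0419), where the feature of that name was lower. Of 93 calls of list genes made both ways, 59 had the same direction and 34 opposite ones.

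Of features called in the same direction at each condition except 90 min, Usp26 (median log2 2.94) and Lgi1 (3.38) were higher and Nkx6-3 (-2.75) and Mras (-2.46) lower in MD. Across 12440 features, which are not independent replicates, the changes in R42A and MD cells correlated at 0.878 (0 min), 0.899 (45 min), 0.409 (90 min), 0.909 (180 min) and 0.912 (240 min).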
